A study of Homo sapiens with 8 samples.

How the data were processed

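The series measured gene expression in MDA-MB-231, a breast cancer cell line, and HT29, a colorectal cancer cell line, each carrying a control shRNA or an shRNA against NRP1 (neuropilin-1). Each of the 4 groups had 2 arrays, 8 in all, and every group was taken from the sample titles. Per the labels' protocols, cells were grown for 24 hours in DMEM with 10% fetal bovine serum, and 1.0 µg of RNA was labelled with Cy3 for one-colour Agilent arrays. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

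Per the file headers, the authors read the spots with Agilent Feature Extraction 11.0.1.1, which also stands in the submitters' processing notes. The deposited scanner files hold linear intensity values per spot, among them a processed signal that Feature Extraction had background-subtracted, the median spot and local background brightness, and flags for spots well above background, saturated or outlying. The deposited value table holds log2 values of the same arrays. Its scale, centring and direction are not given in the sources used here. Set against each array's own scanner values, its columns correlated at 0.995 to 1.00 and ran in the same direction. Every column had a median of 5.80. Equal medians occur with quantile normalization but do not by themselves establish it. Against any other array's scanner values the highest correlation was 0.990.

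Outlier and control spots were left out, spots of one probe were averaged on the log2 scale, and log2 of the processed signal minus each array's 75th percentile was used. Of 34127 probes, 25771 were named by matching their accession, without version, to a RefSeq table of assembly GRCh38.p14, which gave 19740 gene names. The array grid was made on another build, so no coordinates are given. The brightest probe stood for a gene, and probes without a name were kept as single features. A feature was tested if it was well above background on both arrays of at least 1 group, and 28 probes with a missing value were left out. This left 20872 features, of which 15780 were named genes. For 116 genes different probes went opposite ways past the threshold between the lines, and for 0 genes did they do so in the limma comparisons of knockdown and control. Such genes were not named individually. In MDA-MB-231 no gene passed with knockdown, so for that line the 0 does not show that probes agreed.

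The precision is limited by the number of arrays, 2 per group. Depth in reads does not apply to arrays. Between 60.0% and 73.8% of the probes of an array were well above background and 0 spots were saturated. Features not well above background on either array of a group have only a bound there: the fold is then given as "at least", from the brighter group's mean against the higher of the dim probe's own signal and the lowest signal among probes well above background on each array.

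All 8 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient per group), and p-values were adjusted by the Benjamini-Hochberg method over all features, with a threshold of 0.05. The comparisons were shNRP1 against control in each line, the difference between these changes (the interaction), and control MDA-MB-231 against control HT29. Shifts of 39 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Of 1071 list symbols, 1066 were found in the RefSeq table. The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. Under that rule the text names NRP1, the 10 largest rises and falls past the threshold in a knockdown comparison (or the 5 smallest p-values in each direction where none passed), up to 4 members of each list with a camera adjusted p under 0.05 or at least 3 members past the threshold, the 6 most positive and 6 most negative values of the interaction and of the control comparison, and 3 members each of the intestinal, junction, mesenchymal and mammary lists between the lines. Unnamed features, pseudogenes and Y-linked genes were excluded from it. The rises, falls and smallest p-values of a knockdown comparison were taken only from genes whose groups of arrays did not overlap. Their brighter group was also well above background on both arrays. A few genes that the rule names, and a list, are left out of the text.

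The scanner files used here hold no mean spot signal, so the normexp alternative (offset 50) used the median spot signal. Other alternatives were quantile normalization, scaling to the median of detected probes, other filters on dim probes, the mean over a gene's probes, the authors' value table, trended and robust variances, only the arrays of a comparison, the replicate number as a block, and leaving out each array. Array weights, and quantile normalization together with the block, were added after seeing the data. The arrays lay on 2 slides, 1 per cell line, so slide and line cannot be told apart, while each knockdown comparison lies within 1 slide. On both slides the control arrays held positions 1 and 2 and the shNRP1 arrays positions 3 and 4, so position and knockdown cannot be told apart.

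The limma step was tested on simulated arrays with the real control means of each line and the fitted spreads of the 20872 features. Noise was drawn for each gene on its own, so the shares below do not cover errors that genes of an array share. In the MDA-MB-231 comparison the limma step recovered 17% of 100 simulated 2-fold changes and 90% of 50 simulated 4-fold changes. It recovered 100% of 50 simulated 16-fold changes, and of all 113 calls 1 was false. So many true changes ease the Benjamini-Hochberg cut-off. On the real MDA-MB-231 arrays 0 genes passed, and NRP1, 5.22-fold lower, did not. The shares are therefore not the power on those arrays. In the HT29 comparison the shares were 18%, 88% and 100%, with 8 false calls among 122. Figures were drawn with matplotlib.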

Results

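Gene expression was measured on 8 one-colour arrays, 2 for each of control and NRP1-knockdown MDA-MB-231 and HT29 cells. NRP1 encodes neuropilin-1, a cell-surface co-receptor for semaphorins and VEGF family ligands. The comparisons ask which genes differ after knockdown of NRP1 in each line, and whether the lines differ in that response. Replicates correlated across genes at 0.977 to 0.991. Arrays of different arms correlated at 0.976 to 0.989 within MDA-MB-231, at 0.963 to 0.975 within HT29, and at 0.789 to 0.811 between lines. The first principal component held 85.8% of the variance and separated the lines. The next held 5.53% and separated the arms of both lines in the same direction, further in HT29. Its scores were 43.2 and 36.8 in control against -26.0 and -56.7 in shNRP1 HT29. In MDA-MB-231 they were 7.2 and 8.4 against -3.1 and -9.8. The median SD between replicates was 0.121 and 0.208 log2 units in control and shNRP1 MDA-MB-231, and 0.131 and 0.189 in HT29.

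NRP1 itself was lower on every knockdown array than on every control array of the same line. In HT29 it fell 10.5-fold, by 3.40 ± 0.25 (SE) on the log2 scale (limma adjusted p = 0.00316), from a level of 2.29 ± 0.03 (SD, n = 2) to -1.11 ± 0.49 relative to the array's 75th percentile. In MDA-MB-231 the log2 difference was -2.38 ± 0.25 (SE), 5.22-fold lower, between levels of 1.03 ± 0.09 and -1.35 ± 0.20 (SD, n = 2). Its limma adjusted p over all genes was 0.148, although the unadjusted p was 2.46e-05 and the 95% interval ran from -2.96 to -1.80. The other NRP1 probe gave log2 differences of -3.29 in HT29 and -2.83 in MDA-MB-231. NRP1 stayed well above background on all 8 arrays, with 9.49% of the control signal left in HT29 and 19.2% in MDA-MB-231. The change in MDA-MB-231 minus that in HT29 was 1.01 ± 0.35 (limma adjusted p = 0.218), or 0.67 without HT29 shNRP1 replicate 2, and control HT29 had 2.39-fold more NRP1 than control MDA-MB-231 (limma adjusted p = 0.00436). The other probe gave 0.46 for the former (limma adjusted p = 0.602) and no such gap between the control arms, at a log2 difference of -0.18 (limma adjusted p = 0.576), and the mean of both probes gave -0.72. The probes are annotated to different NRP1 transcripts, and whether the lines differ in transcript use was not tested.

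**Figure D1:**
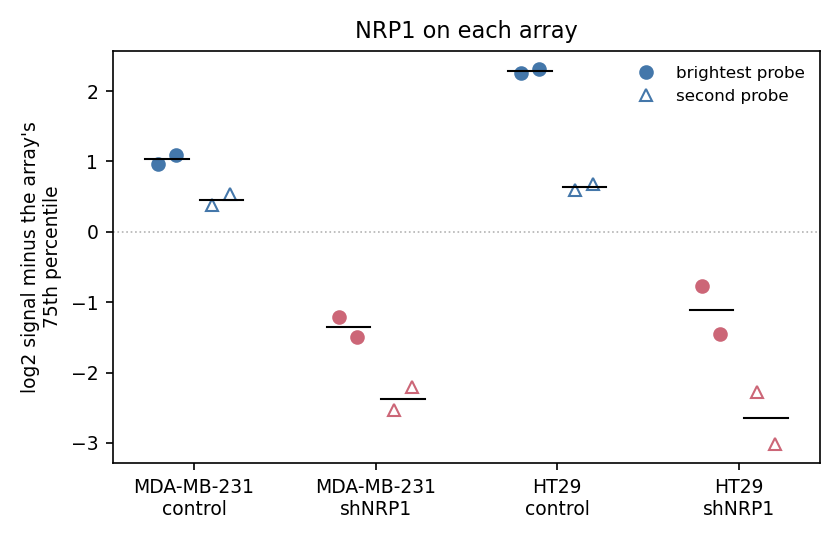
NRP1 signal on each of the 8 arrays (points, log2 minus the array's 75th percentile) for its 2 probes, with the mean of each group as a line. The brightest probe lay at 2.29 on average in control HT29 and at -1.11 after knockdown, and at 1.03 and -1.35 in MDA-MB-231.

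In HT29, 12 of 35 interferon-stimulated and 5 of 18 MHC class I genes fell with NRP1 knockdown, while 7 of 25 intestinal, 5 of 15 stem cell and 8 of 21 Wnt-pathway genes rose, among them TSPAN8, LGR5 and SP5. Other Wnt-pathway genes fell, and lists share members, such as LGR5 in the intestinal and Wnt lists. Among 20872 features tested, 796 rose and 339 fell (1135 in all), of which 596 and 216 changed at least 2-fold. Among the 10 largest fitted rises were AKR1B10 (33.4-fold), AKR1B15 (35.4-fold, with 1 of the 2 control arrays well above background), SP5 (at least 8.48-fold), PRB2 (at least 14.0-fold) and CFTR (at least 23.0-fold). AKR1B10 and AKR1B15 are closely related aldo-keto reductases, PRB2 is a salivary proline-rich protein, and CFTR is the epithelial chloride channel. F5, coagulation factor V, rose at least 5.40-fold, the tight-junction gene CLDN2 21.0-fold, the tetraspanin TSPAN8 18.6-fold, the potassium channel subunit KCNE3 17.7-fold and the guanine deaminase gene GDA rose by 4.09 on the log2 scale. SP5, PRB2, CFTR and F5 were not well above background in control HT29, so they have no rank among the rises. Among the 10 largest fitted falls were SCHIP1 (at least 4.67-fold), the antiviral gene RSAD2 (11.4-fold), GAS6 (at least 3.68-fold), CXCL11 and CCL5 (8.32-fold). SCHIP1 and GAS6 were not well above background in HT29 shNRP1. CXCL11 was well above background on 1 of the 2 shNRP1 arrays, and its fitted log2 change was -1.91 without shNRP1 replicate 2 and -4.56 without replicate 1. That of OASL was -1.75 and that of RSAD2 -2.43 without replicate 2, against -3.69 and -4.59 without replicate 1. The log2 change of AKR1B15 was 4.45 without control replicate 1 and 5.84 without control replicate 2. IL11, also well above background on 1 of the 2 shNRP1 arrays, fell 7.99-fold, HES7 7.57-fold, OASL 6.58-fold, MERTK 6.43-fold and LONRF1 5.74-fold. GAS6 is a ligand of the receptor tyrosine kinases MERTK and AXL, and AXL fell 2.90-fold. The limma adjusted p of these 20 changes ran from 0.00139 for CLDN2 and AKR1B10 to 0.0497 for CXCL11. With normexp background correction, 968 genes rose and 773 fell, a less one-sided split.

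**Figure D2:**
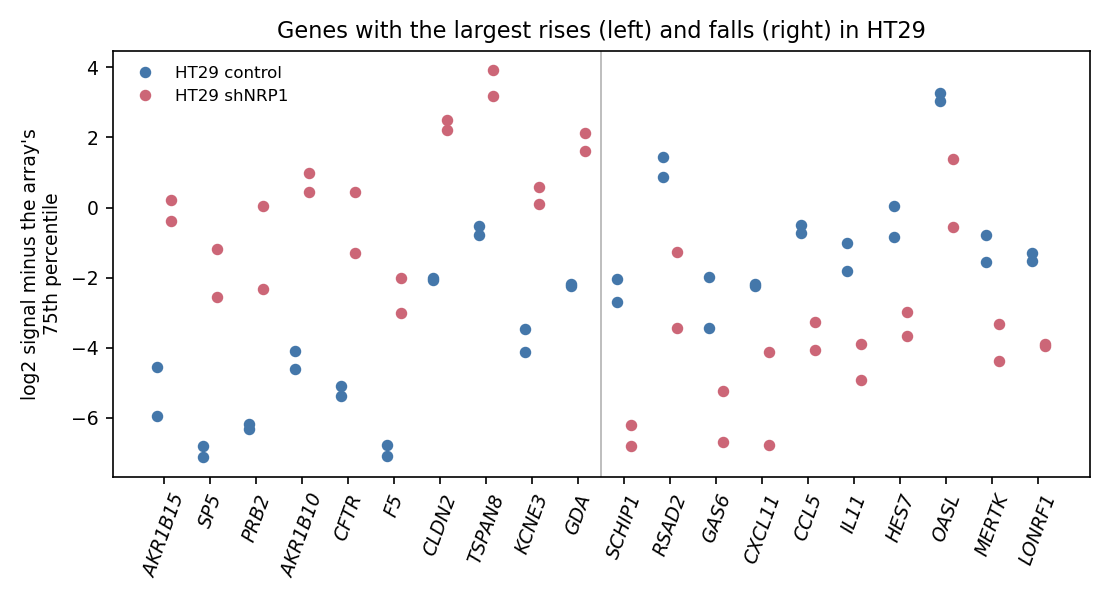
Signal on each HT29 array (points, log2 minus the array's 75th percentile) for the 10 genes with the largest rises and the 10 with the largest falls, control in blue and shNRP1 in red. Only genes whose arms do not overlap were eligible for these 20, and AKR1B10 differs by 5.06 on the log2 scale.

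The type I interferon list, genes induced by interferon alpha and beta, shifted furthest in HT29. Of its 35 measured members 12 fell, 0 rose and 23 did not pass the test, against 32 that fell when adjusted over the list alone, and the median log2 change was -1.77. OAS3 fell 4.64-fold, the viral RNA sensor IFIH1 5.18-fold, the ubiquitin-like ISG15 5.01-fold and RSAD2 11.4-fold. The camera adjusted p of the list was 5.64e-21, and the adjusted p = 0.580 with an estimated correlation. Without HT29 shNRP1 replicate 2 its median was -1.20, and without replicate 1 it was -2.40. Of 18 genes of antigen presentation by MHC class I, 5 fell and 13 did not pass, and 12 fell when adjusted over the list alone. The peptide transporter genes TAP1 and TAP2 fell by 1.89 and 1.86 on the log2 scale, and HLA-B and HLA-C each fell by 1.85. The median of this list was -0.85 (camera adjusted p = 4.06e-10; adjusted p = 0.580 with an estimated correlation). Of 23 NF-kB and inflammatory cytokine genes, 3 fell (CCL5, IL11 and CSF2) and 1 rose, the prostaglandin synthase gene PTGS2, 4.71-fold. CSF2, well above background on 1 of the 2 shNRP1 arrays, had a fitted log2 change of -2.22, and -1.46 without shNRP1 replicate 2. Adjusted over the list alone, 3 rose and 3 fell, and the camera adjusted p was 0.635, with a median of 0.16 against a mean of -0.12.

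Part of the markers of the intestinal epithelium rose in HT29. Of 25 measured, 7 rose, 0 fell and 18 did not pass, with 9 up and 1 down when adjusted over the list alone. The villus gene VIL1 rose 11.2-fold, the stem cell receptor LGR5 13.6-fold (1 of the 2 control arrays well above background), TSPAN8 18.6-fold and the goblet cell gene SPINK4 at least 3.27-fold. The median change of the list was 0.18 and its mean 0.92 (camera adjusted p = 0.0135; adjusted p = 0.580 with an estimated correlation), and without HT29 shNRP1 replicate 1 the camera adjusted p was 0.296. Its median was 0.64 without shNRP1 replicate 2 and 0.31 without control replicate 2. The log2 change of VIL1 was 2.72 without shNRP1 replicate 1 and 4.24 without replicate 2. Of 15 stem cell markers, 5 rose and 10 did not pass, and 5 rose when adjusted over the list alone. Among them ALDH1A1 rose 10.5-fold, the drug exporter gene ABCG2 2.62-fold and PROM1, well above background on 1 of the 2 control arrays, by 2.49 on the log2 scale (1.83 without shNRP1 replicate 1, 3.14 without replicate 2), and the list had a camera adjusted p of 0.165, with a fry adjusted p of 0.0438. Of 21 Wnt targets, 8 rose, 3 fell and 10 did not pass (11 and 4 adjusted over the list alone). SP5, LGR5 and BMP4 (2.11-fold) were among those that rose, whereas the cyclin gene CCND1 fell 4.43-fold. The median of the Wnt list was 0.70 (camera adjusted p = 0.0252; adjusted p = 0.580 with an estimated correlation), and its camera adjusted p was 0.207 without HT29 shNRP1 replicate 1. Among probes well above background on all 8 arrays the Wnt list had a median of 0.42 (camera adjusted p = 0.772) and the intestinal list a median of 0.07, no longer passing. That filter also leaves out genes that rose from background or that MDA-MB-231 does not express.

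Growth-signalling lists lay lower in HT29 after knockdown. Of 20 genes of MAPK pathway output 4 fell, namely CCND1, FOSL1 (3.98-fold, or -1.29 on the log2 scale without shNRP1 replicate 2), EMP1 (2.11-fold) and PHLDA1 (1.80-fold), and 16 did not pass (1 up and 7 down adjusted over the list alone). Of 22 immediate early genes 3 fell and 19 did not pass (6 down adjusted over the list alone), with falls of 3.99-fold for FOSB and 2.99-fold for JUN. MYC, at a log2 difference of -1.04, did not pass (limma adjusted p = 0.0518). Of 21 YAP and TAZ targets 3 fell, CCN1 4.37-fold, AXL 2.90-fold and ASAP1 2.12-fold, and 1 rose, NUAK2 4.35-fold, with 1 up and 6 down adjusted over the list alone. The medians of these lists were -0.42, -0.79 and -0.57, with camera adjusted p of 6.62e-05, 6.62e-05 and 0.000145, and for each the adjusted p = 0.580 with an estimated correlation. Without HT29 shNRP1 replicate 2 the medians of the MAPK, immediate early and YAP and TAZ lists were -0.14, -0.34 and -0.27, and without replicate 1 those of the first pair were -0.78 and -1.26. The YAP and TAZ median was -0.23 with normexp background correction. Of 20 Notch pathway genes 3 fell, HES1 2.09-fold, HES4 3.53-fold and JAG2 2.29-fold, and 17 did not pass (4 down adjusted over the list alone; camera adjusted p = 0.0849).

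The lists of the unfolded protein response, heat shock, hypoxia and glycolysis shifted down by camera as well. Of 35 genes of the unfolded protein response and ATF4, 1 fell, the chaperone HSP90B1 1.95-fold, and 34 did not pass, with 5 down adjusted over the list alone. PPP1R15A had a log2 difference of -2.64 and missed the threshold (limma adjusted p = 0.0503). Its difference was -1.59 without HT29 shNRP1 replicate 2. The list's median was -0.84 (camera adjusted p = 2.96e-08; adjusted p = 0.580 with an estimated correlation), and it was -0.34 without HT29 shNRP1 replicate 2 and -1.29 without replicate 1. Of 22 heat shock genes 4 fell, CHORDC1 2.77-fold, HSPA4L 2.15-fold, HSPA4 1.95-fold and DNAJA4 1.69-fold, 18 did not pass, and 4 fell when adjusted over the list alone. Their median was -0.18 (camera adjusted p = 0.000261; adjusted p = 0.580 with an estimated correlation). Of 31 hypoxia genes 4 fell, among them ADM 5.21-fold, RORA 2.83-fold and the glucose transporter SLC2A1 1.88-fold, and 1 rose, the carbonic anhydrase CA12, at least 3.17-fold (2 up and 7 down adjusted over the list alone). Their median was -0.21 (camera adjusted p = 0.00814; adjusted p = 0.580 with an estimated correlation). Of 19 glycolysis genes 3 fell, PFKP 1.88-fold, HK2 1.77-fold and SLC2A1, and 4 fell when adjusted over the list alone. Their median was -0.12 (camera adjusted p = 0.0252; adjusted p = 0.605 with an estimated correlation). Single HT29 arrays decided several of these calls. Without shNRP1 replicate 1 the camera adjusted p was 0.0710 for heat shock, 0.118 for hypoxia and 0.614 for glycolysis, with medians of -0.03, -0.04 and 0.14. Without control replicate 1 it was 0.0835 for hypoxia and 0.137 for glycolysis, with medians of -0.03 and -0.05. The medians of heat shock, hypoxia and glycolysis were -0.50, -0.47 and -0.29 without shNRP1 replicate 2, and -0.30, -0.53 and -0.20 without control replicate 2. With quantile normalization the glycolysis call ended at a median of -0.15 (camera adjusted p = 0.105). Of 53 cytosolic ribosomal protein genes 1 rose, RPS14 2.01-fold, also when adjusted over the list alone, and the median was 0.17 (camera adjusted p = 0.0253; adjusted p = 0.783 with an estimated correlation). That call ended with quantile normalization (median 0.11, camera adjusted p = 0.0622) and with normexp (median 0.14, camera adjusted p = 0.0653). It also ended without control replicate 2 (median 0.13) or shNRP1 replicate 2 (median 0.07).

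Cell cycle genes differed between the shNRP1 replicates of HT29. Of 40 genes of G1 to S and DNA replication and of 41 genes of G2 and mitosis, 0 passed the limma test, also when adjusted over the list alone. MCM10 had a log2 difference of -0.99, NDC80 -0.66 and ANLN -0.89, and without shNRP1 replicate 1 these were -0.51, -0.41 and -0.24. The medians were -0.32 and -0.35 (camera adjusted p = 0.0252 and 0.000492; adjusted p = 0.783 with an estimated correlation for both). Without shNRP1 replicate 1 the medians were 0.52 and 0.26, and without replicate 2 they were -1.13 and -0.98, so the direction rested on which array was kept. The list of G1 to S and DNA replication also lost its call without control replicate 1, where its median was -0.12. Its median was -0.49 without control replicate 2. With quantile normalization the call ended at a median of -0.33 (camera adjusted p = 0.118).

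Other lists held scattered changes in HT29. Of 26 epithelial junction genes 2 rose, CLDN1 2.77-fold and the keratin KRT8 2.66-fold, and the transcription factor gene OVOL2 fell 2.03-fold, with 2 up and 3 down adjusted over the list alone. Of 44 matrix and integrin genes the protease MMP7 rose 4.17-fold and ITGB8 2.84-fold, whereas LAMC1 fell 2.06-fold, and the same numbers held adjusted over the list alone. Of 22 angiogenic factors EDN1 rose 3.38-fold and VEGFC also passed, although it was not well above background in either HT29 group and so has no fold, and ANG fell at least 1.77-fold (3 up and 2 down adjusted over the list alone). The camera adjusted p of these lists was 0.0579, 0.575 and 0.991 respectively. Markers of endothelial cells, leukocytes and fibroblasts, which the cultures should not hold, had medians of -0.02, 0.12 and 0.06 and camera adjusted p of 0.337, 0.761 and 0.791.

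**Figure D3:**
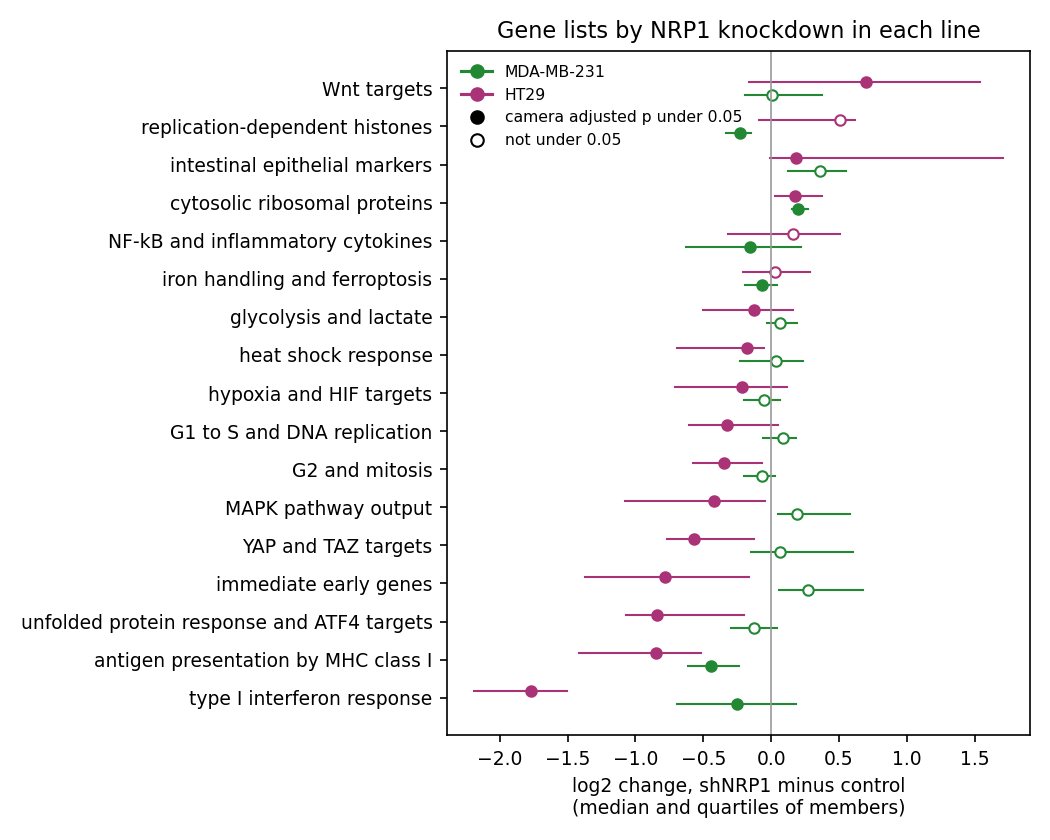
Median log2 change (points) and quartiles (lines) of the members of each gene list with a camera adjusted p under 0.05 in at least 1 line, for MDA-MB-231 in green and HT29 in purple, and filled points where the adjusted p was under 0.05 at the preset correlation. The interferon list lay at -1.77 in HT29 and at -0.25 in MDA-MB-231, and no list kept its call with an estimated correlation.

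The HT29 count depended on single arrays. It was 27 without control replicate 1, 119 without control replicate 2, 2393 without shNRP1 replicate 1 and 640 without shNRP1 replicate 2, and 370 without either control array of MDA-MB-231, which enters through the shared estimate of the spread. It was 3 when only the 4 HT29 arrays were fitted.

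In MDA-MB-231, no gene passed the limma test: 0 of 20872 had an adjusted p under 0.05, against 2104 at an unadjusted p under 0.05. NRP1, 5.22-fold lower, was among the largest differences. The genes with the smallest p were TRIML2 (log2 difference 1.68 ± 0.19), RBBP8NL (1.56 ± 0.19, with 1 of the 2 control arrays well above background), PLEKHB2 (1.06 ± 0.15), the Wnt receptor gene FZD4 (1.35 ± 0.20) and ABCA13 (1.16 ± 0.17) on the higher side. On the lower side they were AMHR2 (-2.52 ± 0.28), TXNDC16 (-1.31 ± 0.16), the focal adhesion genes LPP (-1.44 ± 0.19) and LIMS1 (-1.84 ± 0.24), and STYX (-1.42 ± 0.19). Errors are SEs, and the limma adjusted p of these 10 genes was 0.148 or 0.180. AMHR2, TXNDC16 and LPP were not well above background after knockdown, which bounds their differences at no less than 1.35-fold, 2.25-fold and 1.35-fold lower.

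By camera, 6 of the 39 lists shifted in MDA-MB-231, 1 up and 5 down, with no member of any list past the threshold over all genes. The 18 MHC class I genes had a median of -0.44 (camera adjusted p = 8.86e-06; adjusted p = 0.834 with an estimated correlation), 0 of them passing when adjusted over the list alone. Their values included -0.62 for TAP2, -0.66 for HLA-F and -0.47 for the immunoproteasome subunit PSMB8, and those of TAP2 and HLA-F were -0.31 and -0.39 without shNRP1 replicate 2. The 35 interferon genes had a median of -0.25 (camera adjusted p = 0.00333; adjusted p = 0.942 with an estimated correlation), with -2.15 for IFIT2 and -1.76 for OASL, -2.15 for IFI44, which was well above background on 1 of the 2 shNRP1 arrays, and at least 2.67-fold lower IFIT3, which was so on neither, and 0 passing when adjusted over the list alone. With normexp background correction the interferon median was -0.07, and it was -0.12 without MDA-MB-231 control replicate 2 and -0.14 without shNRP1 replicate 1. The MHC class I median was -0.20 without shNRP1 replicate 2. The 23 NF-kB and cytokine genes had a median of -0.16 (camera adjusted p = 0.00418; adjusted p = 0.730 with an estimated correlation), which was 0.13 with normexp background correction and -0.29 without control replicate 1. Of these 1 fell when adjusted over the list alone, and the log2 differences were -1.34 for CCL2, -0.51 for SOD2 and -1.22 for BIRC3, the last -0.56 without shNRP1 replicate 2.

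The 33 replication-dependent histone genes had a median of -0.23 (camera adjusted p = 0.000474; adjusted p = 0.939 with an estimated correlation). Without MDA-MB-231 shNRP1 replicate 2 that median was 0.02 and the call ended (camera adjusted p = 0.768), without replicate 1 it was -0.42, and without control replicate 1 it was -0.14. The 30 genes of iron handling and ferroptosis had a median of -0.06 (camera adjusted p = 0.0400; adjusted p = 0.834 with an estimated correlation), with -1.42 for the quinone reductase NQO1, -1.23 for the cystine transporter SLC7A11 (-0.73 without shNRP1 replicate 2) and -0.51 for ACO1. This call ended without control replicate 1 (camera adjusted p = 0.0885), control replicate 2 (0.0610) or shNRP1 replicate 2 (0.652), and the median was -0.16 without shNRP1 replicate 1. The 53 ribosomal protein genes had a median of 0.20 (camera adjusted p = 0.00230, and 0.942 with an estimated correlation), with 0.33 for RPS13. This call ended with normexp (median 0.11, camera adjusted p = 0.702) and with quantile normalization (median 0.06, camera adjusted p = 0.273). It also ended without control replicate 2 (median 0.14) or shNRP1 replicate 1 (median 0.15). In each of these last 3 lists 0 members passed when adjusted over the list alone.

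The response to knockdown differed between the lines for 18 genes by the limma interaction test, 2 with a higher and 16 with a lower change in MDA-MB-231 than in HT29. All 18 also passed in HT29, and 0 did in MDA-MB-231. The interaction was -4.62 ± 0.29 (SE) for the RAS-related GTPase gene MRAS, -4.51 ± 0.35 for GDA and -4.40 ± 0.28 for CLDN2, and in the opposite direction 2.62 ± 0.29 for CCN1, which fell by 2.13 in HT29. These 4 genes were well above background in every group. AKR1B10 passed too, but was not well above background in either MDA-MB-231 group. SP5 and the metalloprotease gene ADAMTS6 were not so in control HT29, nor was SCHIP1 in HT29 shNRP1, so their differences between the lines have no exact value. The limma adjusted p of these 8 genes ran from 0.0103 for CLDN2 and MRAS to 0.0488 for SP5, SCHIP1 and CCN1. With normexp background correction 127 genes passed (50 higher, 77 lower), and 81 with the values of the authors (18 higher, 63 lower). The count was 0 without any 1 of the 4 control arrays (2144 to 2583 at an unadjusted p under 0.05), 29 without MDA-MB-231 shNRP1 replicate 1, 2 without its replicate 2, and 750 without HT29 shNRP1 replicate 1.

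By camera 10 lists shifted differently between the lines, among them the interferon list (median difference 1.36, camera adjusted p = 1.06e-09; adjusted p = 0.703 with an estimated correlation). The immediate early genes (1.15), the YAP and TAZ targets (0.79), the MAPK output genes (0.75), the MHC class I genes (0.48), the heat shock genes (0.40) and the junction genes (0.34) also had a higher change in MDA-MB-231, each with adjusted p = 0.703 with an estimated correlation. So did the unfolded protein response genes (0.55; adjusted p = 0.810 with an estimated correlation). The histone genes had a lower change in MDA-MB-231 (-0.66; adjusted p = 0.810 with an estimated correlation), and so had the Wnt targets (-0.53; camera adjusted p = 0.0499, and adjusted p = 0.703 with an estimated correlation). Without HT29 shNRP1 replicate 2 the medians were 0.73 for the interferon list, 0.55 for the immediate early, 0.46 for the YAP and TAZ, 0.36 for the MAPK, 0.31 for the MHC class I, 0.71 for the heat shock and 0.07 for the unfolded protein response genes, the last no longer passing (camera adjusted p = 0.458), and the junction call ended as well (0.0941). Without HT29 shNRP1 replicate 1 the unfolded protein response median was 0.99. The calls of the histone (median -0.30), heat shock (median 0.32) and Wnt (median -0.54) lists ended there. Without MDA-MB-231 shNRP1 replicate 1 the calls of 4 lists ended. Their medians were 0.25 for MHC class I, 0.56 for heat shock, 0.48 for the unfolded protein response and -0.48 for Wnt. Without its replicate 2 the calls of the histones (median -0.43) and the Wnt list (median -0.29) ended. The Wnt call also ended without control replicate 1 of either line (median -0.49 for MDA-MB-231, -0.42 for HT29). The heat shock call ended without HT29 control replicate 1 (median 0.34). With quantile normalization the call of the Wnt targets ended at a median of -0.70 (camera adjusted p = 0.0685). That of the junction genes ended as well, at a median of 0.18 (camera adjusted p = 0.133). Among features well above background on all 8 arrays the junction call ended at a median of 0.15 (camera adjusted p = 0.355). The Wnt call ended there too, at a median of -0.29 (camera adjusted p = 0.924). That filter leaves out genes that are dim in either line.

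No gene passed in both lines: the count was 0, with 0 from overlap of independent lists, since 0 genes passed limma in MDA-MB-231 (2104 at an unadjusted p under 0.05). Across all 20872 features the log2 changes of the lines correlated at r = 0.08 (Spearman 0.07), and 55.0% had the same sign. Genes are not independent replicates, so these values carry no p. The median change over all features was 0.09 in each line, which by itself raises the share with the same sign. The lowest signal among probes well above background also lay higher on the shNRP1 arrays of both lines. Relative to the 75th percentile it was -4.16 and -4.15 in control against -3.79 and -3.75 in shNRP1 MDA-MB-231. In HT29 it was -5.02 and -4.87 against -4.53 and -4.64. How far dim features raise the share with the same sign was not tested. Of the 796 genes that rose in HT29, 60.9% were higher in MDA-MB-231 as were 61.3% of all features, and of the 339 that fell, 46.0% were lower, against 38.7% of all features.

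**Figure D4:**
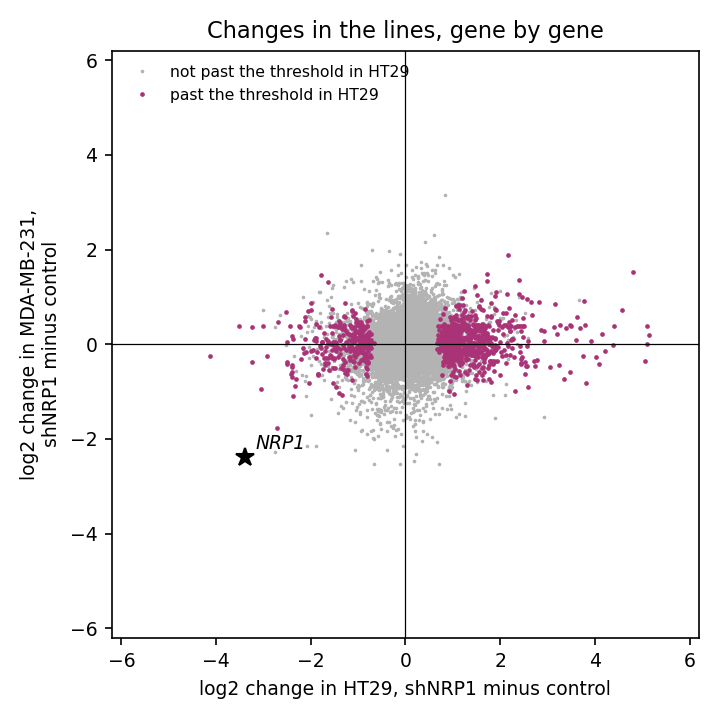
Log2 change with NRP1 knockdown in HT29 (horizontal) against that in MDA-MB-231 (vertical), 1 point per named gene, with genes past the threshold in HT29 in purple and NRP1 as a star at -3.40 and -2.38. Over all 20872 features the changes correlated at r = 0.08.

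The control arms of the lines differed for 12058 of 20872 features, 4979 higher in MDA-MB-231 and 7079 higher in HT29. Mesenchymal genes were mostly higher in MDA-MB-231 and epithelial ones in HT29. The intermediate filament gene VIM was 1060.3-fold higher in MDA-MB-231, LOXL2 130.4-fold and LOX at least 41.9-fold. Of 21 mesenchymal genes 13 were higher in MDA-MB-231, 7 in HT29 and 1 did not pass, with the same numbers adjusted over the list alone. Of 26 epithelial junction genes 21 were higher in HT29 and 2 in MDA-MB-231, also adjusted over the list alone, among them RAB25 (at least 175-fold), GRHL2 (at least 46.4-fold) and OVOL2 (at least 26.7-fold). Of 25 intestinal markers 17 were higher in HT29 and 3 in MDA-MB-231, also adjusted over the list alone. AGR2 was 120.4-fold and LGALS4 106-fold higher in HT29, and CEACAM5 at least 1.55-fold. Of 19 mammary and luminal markers 6 were higher in MDA-MB-231 and 12 in HT29 (6 and 13 adjusted over the list alone). MUC1 was 98.6-fold higher in MDA-MB-231, and MIA at least 85.8-fold higher in HT29.

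Among the largest fitted differences towards MDA-MB-231 were those of the urea cycle gene CPS1 (at least 1095-fold), SPINK6 (at least 718-fold), PXDN (at least 676-fold), the hormone subunit gene CGA (at least 569-fold), CCN5 (at least 1128-fold) and the lipase gene LPL (at least 439.9-fold), none of them well above background in control HT29. Those towards HT29 included EREG (at least 355-fold), PADI1 (at least 654-fold), FGF19 (at least 262-fold), TMEM45B (at least 175-fold), RAB25 and AMIGO2 (at least 125-fold). The limma adjusted p of these 12 genes ran from 5.08e-07 to 1.27e-05. The names of the lines are those of the labels, and their identity was not tested against a reference profile. Each line lay on its own slide, so that slide and line cannot be told apart. Over all features the median difference was -0.21, and it was -0.01 with normexp background correction, which gave 5366 genes higher in MDA-MB-231 and 5087 higher in HT29.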

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

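All tests of explanations in this part were chosen after the results were seen, except that of neighbouring genes, and the test of dim probes replaced an earlier form whose result had been seen.

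The change with NRP1 knockdown differed between MDA-MB-231 and HT29 for 18 genes by the limma interaction test. The fitted change in MDA-MB-231 minus that in HT29 was -5.42 for AKR1B10, -5.10 for SP5, -4.62 for MRAS, -4.51 for GDA, -4.40 for CLDN2, -4.31 for ADAMTS6, -4.02 for F5 and -3.92 for KCNE3. It was 3.89 for SCHIP1 and 2.62 for CCN1. The values of SP5, F5 and ADAMTS6 (not well above background in control HT29), of SCHIP1 (not so in HT29 shNRP1) and of AKR1B10, F5 and KCNE3 (not so in either MDA-MB-231 group) set a measured signal against background, so their size is not measured. The camera test also separated the lines for 10 lists, with median differences of 1.36 for the type I interferon response, 1.15 for immediate early genes, 0.79 for YAP and TAZ targets, 0.75 for MAPK pathway output, 0.55 for the unfolded protein response and ATF4 targets, 0.48 for MHC class I antigen presentation, 0.40 for the heat shock response, 0.34 for epithelial junction genes, -0.53 for Wnt targets and -0.66 for replication-dependent histones. The adjusted p of these lists ran from 0.703 to 0.810 with an estimated correlation. The calls of the junction and Wnt lists ended among features well above background on all 8 arrays.

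Interferon and MHC class I genes lay lower in HT29 shNRP1. Dilution by MDA-MB-231 RNA would need a share of 70.7%, whereas 80 genes that were far higher in control MDA-MB-231 gave a median apparent share of 0.0305%. Scaling was argued against by the interferon median closest to 0 over 4 scaling and background alternatives, -1.42, and a single HT29 array by the median closest to 0 without each of those arrays, -1.20. A difference between the control and NRP1 shRNA vectors in the interferon response they provoke, the position of the arms on the slide, and an effect of NRP1 loss stay open, the last as a hypothesis, because the labels name no shRNA sequence and no untransduced cells.

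Rises outnumbered falls in HT29 shNRP1, with AKR1B10, SP5, CLDN2, TSPAN8 and LGR5 among them. The median change over all features was 0.09 in HT29, and with normexp the split was less one-sided. Scaling as a source of the split was not tested. At the upper quartile of the apparent share, 0.125%, MDA-MB-231 RNA would give at least 0.5 of the rise for 0.126% of the 796 risen genes. A higher floor of dim probes as the source of most rises was argued against by 74.0% of the 596 rises of at least 2-fold being well above background on all 4 HT29 arrays, and the remaining ones stay open to it. For a copy-number difference between the arms, the largest median shift of 50 neighbouring genes was 0.32, which 17 of 1000 shuffled gene orders matched but which lay below the highest of them, 0.36. The prediction for a cause was met in part only, and whether that counts was settled after the value was seen. The explanation therefore cannot be told apart from genes that are regulated together. Clonal differences between the arms and their position on the slide remain open beside an effect of NRP1.

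No gene passed the limma test in MDA-MB-231, where 0 had an adjusted p under 0.05 and 2104 an unadjusted p under 0.05, against 1135 passing in HT29. The ratio of the median SDs between replicates, MDA-MB-231 over HT29, was 0.980. This ratio cannot decide on a larger spread in MDA-MB-231, because the joint fit gives both lines the same SE for a gene. At the same SE, fewer passing genes already mean smaller changes, so their size describes the count and does not explain it. Over 15375 features well above background on all arrays, the SD of the changes less the replicate noise was 0.180 in MDA-MB-231. It was 0.426 in HT29, a ratio of 0.423. Less loss of NRP1 in MDA-MB-231 stays open, since the loss differed by 1.01 (95% interval 0.19 to 1.84) with a limma adjusted p of 0.218 over all genes by the brighter NRP1 probe, and by 0.46 with an adjusted p of 0.602 by the other.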

How the results depend on the processing

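Array weights and quantile normalization with the block were chosen after seeing the data. The count in MDA-MB-231 was 0 and that of both lines 0 in every limma setting run, with 1120 to 3693 genes at an unadjusted p under 0.05 without single arrays in MDA-MB-231. Against 1135 genes in HT29, the count of genes passing was 1741 with normexp (968 higher, 773 lower, 919 shared), 709 without a filter on dim probes, 571 with the replicate block, 318 with quantile normalization and the block, and 3 with only the arrays of the comparison, where fewer arrays estimate the spread. It ran from 27 to 2393 without single arrays: 27 and 119 without control replicates 1 and 2, 2393 and 640 without shNRP1 replicates 1 and 2, and 370 without either MDA-MB-231 control array. NRP1 in HT29 kept its log2 change of -3.40 but had a limma adjusted p of 0.0550 with only the arrays of the comparison. Against 18 genes in the interaction, the count of genes passing was 127 with normexp (13 shared), 38 with quantile normalization, 8 without a filter, 91 with features well above background on all 8 arrays, 30 with the mean over probes, 81 with the authors' value table, 56 with trended and robust variances, 0 with the replicate block (3845 at an unadjusted p under 0.05) and 0 with quantile normalization and the block (3729), and from 0 to 750 without single arrays: 0 without any 1 of the 4 control arrays, 29 and 2 without MDA-MB-231 shNRP1 replicates 1 and 2, and 750 without HT29 shNRP1 replicate 1. The 6 lists in MDA-MB-231 became 13 with normexp and 12 with only the arrays of the comparison, and 4 to 13 without single arrays (13 without either HT29 shNRP1 array). The 14 lists in HT29 became 11 to 16 without single arrays, and the 10 lists of the interaction 6 (without MDA-MB-231 shNRP1 replicate 1) to 16 (without HT29 shNRP1 replicate 2). With an estimated correlation the counts of lists were 0, 0 and 0, and with fry 0, 1 and 0. Control lines differed for 8792 to 12600 genes without single arrays. In MDA-MB-231, ERAP2 and CCL5, which were not well above background after knockdown, reversed with normexp, to 0.0175 and 0.17. For the results above whose value moved, the cause was not tested unless named. Of the 1853 values of named genes in HT29 under alternatives, 1406 kept their direction and side of the threshold, 396 lost the call, 51 gained it and 0 reversed. Deviations of arrays with the same replicate number correlated across genes at 0.38 in MDA-MB-231 and -0.04 in HT29. The labels do not say that a number marks a shared batch or day, so the numbers were not taken to pair the arrays, which the correlation in MDA-MB-231 leaves open for that line. With the replicate block the Wnt call ended in HT29 (camera adjusted p = 0.0624) and in the interaction (0.0716). The slide and scan blocks were not run, because each comparison of arms lies within 1 slide. Leaving out an array leaves 1 in its group, which is assumed to vary like the others. Signal over background limits the dim genes: folds against a group with no array well above background are bounds.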

Other observations

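Several aldo-keto reductase genes of the AKR1B and AKR1C groups rose in HT29 after NRP1 knockdown. Families were tested after the HT29 results were seen, over 269 families of at least 8 named genes sharing a symbol stem, in both directions. Aldo-keto reductases are enzymes that reduce aldehydes and ketones. Of 12 measured genes with their symbol stem, AKR, which include the pseudogene AKR7A2P1, 5 rose, 0 fell and 7 did not pass (hypergeometric test, one-sided, adjusted p = 0.0327). AKR1B1 rose 13.5-fold, AKR1C3 4.01-fold and AKR1C4 3.07-fold, besides AKR1B10 and AKR1B15. AKR1C1, with a log2 difference of 1.29, did not pass (limma adjusted p = 0.0732). In MDA-MB-231 the log2 differences were -0.25 for AKR1B1, -0.66 for AKR1C3 and -0.99 for AKR1C1, none past the threshold. The AKR1B and AKR1C genes are close paralogs, so their probes are not independent, and the p, which takes them as independent, does not show a rise of the family. No other family passed: 6 of 52 EIF genes fell (adjusted p = 0.111), 4 of 16 ALDH genes rose (adjusted p = 0.260), and 3 of 10 IRF genes (adjusted p = 0.128) and 3 of 11 CXCL genes (adjusted p = 0.131) fell.

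In MDA-MB-231 the largest median shift of 50 neighbouring genes was 0.36 in size, beyond all of 1000 shuffled gene orders, of which the highest was 0.25. Of 304 windows, 1 lay beyond that highest value, with all tested named genes included, dim ones too. Shuffling breaks up neighbours that are regulated together, so a copy-number difference between the arms cannot be told apart from these.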
